A study of Homo sapiens with 12 samples.

How the data were processed

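RNA was measured by sequencing in 12 libraries of PC-3 cells, 3 in each of 4 groups: vehicle (DMSO), palbociclib (5 µM, 24 h), a control hairpin (shControl) and a hairpin against RB1 (shRB1). Per the labels, cells were at passages 25 to 28, RNA was extracted with RNeasy columns and libraries were made from total RNA with an Illumina kit. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.6 to the human genome (hg19, also named GRCh37). The counting tool, the annotation, the strandedness and the sequencing batches are not given in the sources used here. Per the file headers, the deposited values are counts (whole fragments per gene) and FPKM (fragments per kilobase of mRNA size, scaled to library size), one file per library with coordinates and mRNA size per gene. It was checked that the counts, values scaled to library size, mRNA sizes and FPKM of each library are tied by this definition for every gene. Fragments over overlapping genes appear to be counted for each of them, since the values scaled to library size sum to more than they could without double counting.

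Each file held 27734 entries for 27281 symbols. Among the 849 entries of repeated symbols, each symbol kept the entry with the highest total count. Samples were grouped by their labels alone. The fixed plan assumed FPKM and named edgeR on counts as the test if counts were held, and counts were held, so edgeR was used. Counts were normalised with TMM, filtered with edgeR filterByExpr, which left 17561 genes, and fitted by quasi-likelihood (edgeR 4.0.16, R 4.3.3) with all 12 libraries and 4 group terms in one model with 8 residual degrees of freedom. The contrasts tested were 4, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. They were palbociclib against DMSO, shRB1 against shControl, the difference of these 2 effects, and shControl against DMSO. Per-gene means and SDs are of the deposited FPKM.

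There were 22 gene lists with 654 members, fixed before the data were examined: DNA replication and G1/S, mitosis and G2/M, homologous recombination and Fanconi repair, RB family with cyclins, CDKs and their inhibitors, NF-kappaB targets, interferon-stimulated genes, MHC class I antigen presentation, immune checkpoint ligands, senescence-associated proteases and growth factors, p53 targets, replication-dependent histones, cholesterol synthesis, lysosome, unfolded protein and integrated stress response, hypoxia response, MYC and ribosome biogenesis, epithelial, mesenchymal, androgen receptor and luminal prostate, neuroendocrine and neural, and blood and fibroblast and endothelial markers. A list with at least 5 tested members was tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists, and beside it with camera at an estimated correlation and with fry. Camera compares a list with the other genes, and fry does not. List tests of shControl against DMSO were not part of the plan. The comparisons, the tests, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined.

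By that rule the text names RB1 in every library, 8 further genes whatever their test (CD274, PDCD1LG2, CDK4, CDK6, CCND1, CCNE1, CDKN1A and RELA), per comparison up to 10 genes of largest rise and 10 of largest fall among those past the threshold with a group mean of at least 1 FPKM and no overlap of the 2 groups, up to 4 members of each passing list, and the 5 largest differences of effects in each direction. Of these genes, the text prints a selection made after their values were seen, of genes that kept their call with each library left out unless stated. SNAI2 and ZEB2 lie outside the rule. Values of 3 list members are not reported. Chance gives groups without overlap for 10% of genes with 3 libraries against 3. Among all genes tested the groups did not overlap for 62.7% in palbociclib against DMSO, 58.9% in shRB1 against shControl and 23.2% in shControl against DMSO. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so single genes were tested by the model alone.

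Where a group held no fragment of a gene, a fold is given as a bound with a floor of 3 fragments over the group, and with 1 to 3 fragments the ratio is given with a 95% counting interval. Intervals of this kind and floors cover counting error only. Fitted fold changes of such genes depend on the prior count. Depth is given per library as the sum of its gene counts, 23120618 to 48690905 fragments.

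The procedure was tested on simulated counts with the abundances, library sizes and dispersions of these libraries, with 100 genes changed 2-fold and 100 changed 4-fold. For palbociclib against DMSO it recovered 13% of the 2-fold and 81% of the 4-fold changes, for shRB1 against shControl 15% and 82%, and for the difference of effects 2% and 45%. The share of calls that were false was 7.84%, 8.49% and 4.08%, above the nominal 5% in the first 2. A shift of a simulated list of 40 genes passed in each, and no other list was called. The simulated genes were drawn independently of each other. False calls of lists whose members move together, such as mitosis genes (estimated correlation 0.205 for palbociclib), were therefore not tested. At these recovery rates weak changes can be missed, in the difference of effects above all. The simulation changed far fewer genes than passed in the libraries, so its rates need not hold for them. It also gave all groups the same dispersion per gene. In the libraries, the SD over genes of the log2 deviation from group mates was 0.897, 1.48 and 0.602 in shControl 1 to 3. In the others it was at most 0.413. False shares of contrasts that use shControl were therefore not measured under its larger spread.

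Replicate numbers were checked as possible pairs by correlating deviations from the group mean over 11996 genes. Between palbociclib and DMSO libraries of the same number r was 0.461, 0.238 and 0.677, and between shRB1 and shControl libraries -0.580, 0.416 and 0.635. The highest r with another number was 0.176, 0.548 and -0.223 in the first comparison and 0.744, 0.554 and -0.369 in the second, so replicate 2 deviated more with another number in both. By the rule used (r over 0.1 for every number) the first comparison counts as paired and the second does not. Deviations from group mates also followed GC content, with a Spearman rho of -0.38, -0.64 and 0.56 in DMSO 1 to 3. In palbociclib 1 to 3 rho was -0.62, -0.25 and 0.72. The r between libraries therefore cannot tell pairs from a shared bias of this kind. Since the plan named no block, the blocked model is an alternative.

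Alternatives fixed before the data were examined were limma on log2(FPKM + 1), with a filter of 1 FPKM in 3 libraries (14323 genes), a pseudocount of 0.1, quantile normalization, no variance trend or array weights, DESeq2 1.42.0, median-of-ratios size factors, no filter, a filter of 5 FPKM, the 2 compared groups alone, a replicate block, a minimum log2 fold change of 1, and leaving out each library in turn. Added after the data were seen were a correction of each library's trend with GC content and mRNA size (GC content from the longest GENCODE version 29 transcript, found for 24776 symbols), that correction with the block, palbociclib and DMSO alone with the block, the model without DMSO 3 and shControl 2, and the model without shControl 2 with the GC and length correction. All 12 libraries were kept in the reported model. Exon-level reads, protein levels and other data of the study were not analysed here.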

Results

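RNA sequencing measured gene expression in PC-3, a human prostate cancer cell line, at passages 25 to 28. The 12 libraries form 4 groups of 3. One pair of groups was treated with vehicle (DMSO) or with 5 µM palbociclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6, for 24 h. The other pair carried a control hairpin (shControl) or a hairpin against RB1 (shRB1). The counts summed over genes ranged from 23120618 fragments in shControl 2 to 48690905 in DMSO 2. The other DMSO libraries had 43834486 and 37986356, palbociclib 1 to 3 had 23776839, 34895678 and 40739099, shControl 1 and 3 had 41993157 and 40554195, and shRB1 1 to 3 had 45419167, 40813733 and 33859115. The labels do not say that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

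RB1, the gene that the hairpin targets, was measured first in every library. Its level was 11.2, 11.1 and 5.45 FPKM in DMSO 1 to 3, and 10.1, 9.45 and 8.42 FPKM in palbociclib 1 to 3. It was 11.8, 0.492 and 8.25 FPKM in shControl 1 to 3, and 11.2, 11.3 and 13.0 FPKM in the libraries labelled shRB1. The RB1 transcript was therefore not lower in the libraries labelled shRB1 (log2 fold change 0.71, 95% interval -0.78 to 2.19, adjusted p = 0.40), and its lowest value lay in a control library. Without shControl 2 the log2 fold change was 0.18 (95% interval -0.38 to 0.74), and without shControl 1 it was 1.30. Without shControl 2 and with a correction for GC content and length, it was -0.10 (95% interval -0.43 to 0.23). Because RB1 goes against the label, every direction below refers to the libraries labelled shRB1 and not to cells shown to have less RB1. The RB1 span overlaps LPAR6, so part of these fragments could belong to either gene.

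shControl 2 stood apart from the other libraries. Transcripts under 1000 nt gave 15.5% of its fragments, against 4.13 to 7.04% in the others, and transcripts over 4000 nt gave 18.9%, against 32.6 to 43.0%. Its 100 most abundant genes held 23.2% of its counts and its mean correlation with its group mates was 0.905. The mean GC content of annotated transcripts, weighted by its counts, was 54.4%, and the GC content of reads was not measured. Among the fixed gene lists its median deviation from its mates was -1.08 on the log2 scale for mitosis genes, -1.02 for homologous recombination genes, 1.02 for antigen presentation genes and 0.56 for replication-dependent histones.

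**Figure D1:**
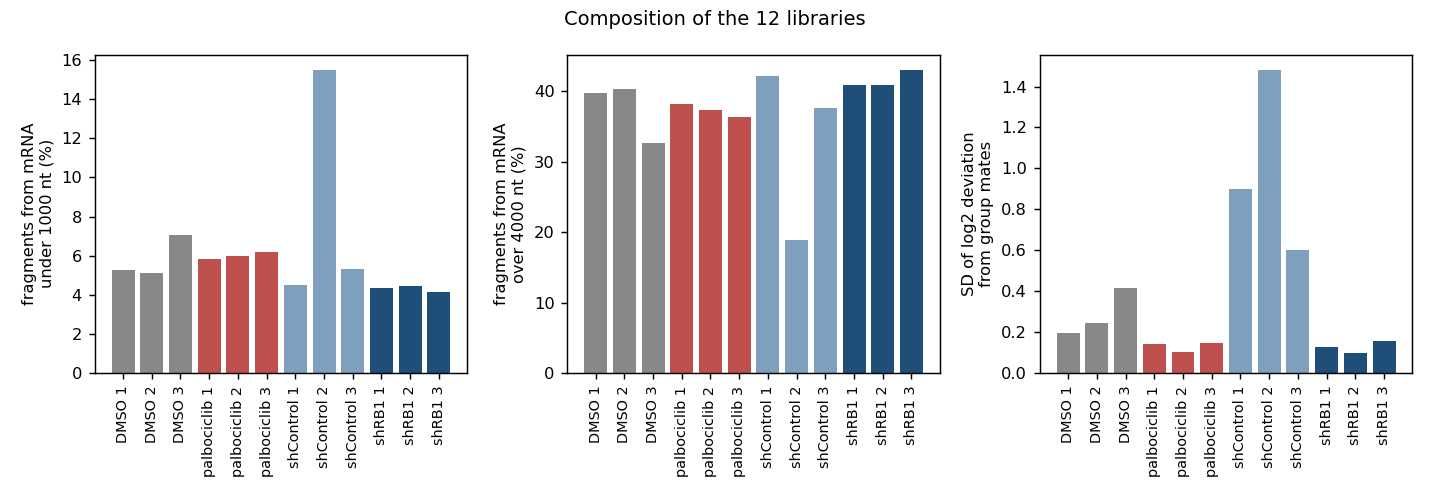
Bars give for each of the 12 libraries the percent of fragments from transcripts under 1000 nt, the percent from transcripts over 4000 nt, and the SD over genes of the log2 deviation from the other libraries of its group. In shControl 2 these are 15.5%, 18.9% and 1.48, the farthest from the other 11 libraries in each panel.

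The first comparison asked what palbociclib changed against vehicle. CD274, which encodes the immune checkpoint ligand PD-L1 (chromosome 9, 5450503 to 5470567, build hg19), rose from 2.70 ± 0.264 FPKM in DMSO to 11.2 ± 0.961 FPKM (SD, n = 3 libraries each), a log2 fold change of 2.04 (SE 0.19, edgeR quasi-likelihood adjusted p = 2.46e-05). PDCD1LG2, the gene of the related ligand PD-L2, fell from 1.37 ± 0.0659 to 0.433 ± 0.0898 FPKM (log2 fold change -1.68, SE 0.21, adjusted p = 1.74e-04). CDKN1A, whose product p21 inhibits cyclin-dependent kinases, rose from 13.2 ± 0.697 to 114 ± 5.79 FPKM (log2 fold change 3.10, SE 0.16, adjusted p = 7.52e-07), and its span overlaps the transcript DINO. CCNE1, which encodes cyclin E1, fell from 12.4 ± 1.22 to 7.43 ± 0.137 FPKM (log2 fold change -0.75, adjusted p = 6.16e-03). In all 4 of these genes the 3 palbociclib libraries lay on one side of the 3 DMSO libraries. RB1 (log2 fold change -0.01, adjusted p = 0.997), CDK4 (0.17, adjusted p = 0.592), CDK6 (0.42, adjusted p = 0.516) and CCND1, the cyclin D1 gene (-0.11, adjusted p = 0.708), did not pass. RELA, which encodes the NF-kappaB subunit p65, had a log2 fold change of -0.25 (adjusted p = 0.151), which passed without shControl 2 (-0.25, adjusted p = 0.00777).

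**Figure D2:**
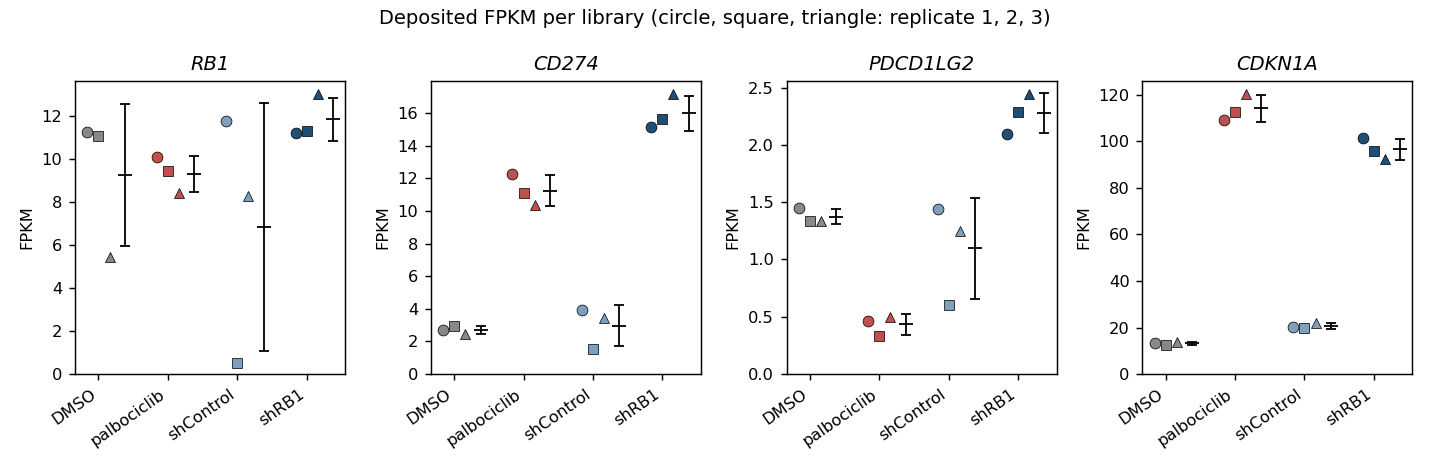
Points give the deposited FPKM of RB1, CD274, PDCD1LG2 and CDKN1A in each library (circle, square and triangle for replicates 1, 2 and 3), with the mean and SD of each group of 3. CD274 averages 11.2 FPKM in palbociclib and 16.0 in the libraries labelled shRB1, while RB1 is lowest in shControl 2, at 0.492 FPKM.

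Over all 17561 genes tested, 5245 passed, of which 2697 rose and 2548 fell. At least a 2-fold change was seen in 1756 and 1380 of these. Without shControl 2, which entered through the shared estimate of spread, 10584 genes passed, and all 5245 were among them. ARC, an immediate early gene of neurons, rose from 2.24 ± 0.325 to 709 ± 64.2 FPKM (log2 fold change 8.29, SE 0.41, adjusted p = 4.52e-07). TBR1, a transcription factor of the developing cortex, rose from 0.00846 to 5.31 FPKM (log2 fold change 9.18, adjusted p = 1.55e-06). CETP, the cholesteryl ester transfer protein gene, held no fragment in DMSO and 410 in palbociclib, and was at least 178-fold higher with a floor of 3 fragments over the group. NPPC, the gene of C-type natriuretic peptide, went from 2 fragments to 501, a ratio of 326 (95% counting interval 89.9 to 2702). The paralogs FCGR1A and FCGR1B, which encode an Fc receptor, also rose (log2 fold changes 8.46 and 9.25), but their sequences are near-identical and FCGR1A overlaps HIST2H2BF, so how fragments divide between them is uncertain. Among the falls, IL1B, the interleukin-1 beta gene, went from 923 ± 22.6 to 40.1 ± 0.914 FPKM (log2 fold change -4.54, SE 0.20, adjusted p = 2.60e-07). SLITRK6, a neuronal transmembrane protein gene, fell by 4.83 on the log2 scale, and HAS2, a hyaluronan synthase gene with an overlapping antisense transcript, fell by 4.04. SOX21, a transcription factor gene, fell from 14.0 to 0.926 FPKM, and FOXQ1, a forkhead factor gene, from 5.04 to 0.410 FPKM.

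Of the cell cycle lists under palbociclib, replication, mitosis and recombination passed as lower and replication-dependent histones as higher. Of 54 tested genes of DNA replication and G1/S, targets of E2F factors, 19 fell, 2 rose and 33 did not pass, and adjusted over the list alone 21 fell and 2 rose (camera adjusted p = 0.00178; adjusted p = 0.0761 with an estimated correlation). E2F2 fell by 1.86 on the log2 scale and RMI2 by 1.67. Of 52 genes of mitosis and G2/M, 9 fell and 1 rose, or 6 and 1 adjusted over the list alone (adjusted p = 0.0113; adjusted p = 0.418 with an estimated correlation), among them HJURP (-0.89), CCNB2 (-0.78) and CENPA (-0.69). Of 25 genes of homologous recombination and Fanconi repair, 4 fell and none rose, with 3 falling adjusted over the list alone (adjusted p = 0.0462; adjusted p = 0.412 with an estimated correlation). RAD54L changed by -1.37 and MND1 by -1.35. This list did not pass without DMSO 2 (adjusted p = 0.0652) or palbociclib 3 (0.0567), with these groups alone (0.0558, or 0.0579 with the replicate block), at 5 FPKM (0.0592), with limma and a pseudocount of 0.1 (0.0548) or with median-of-ratios factors (0.0521). Without shControl 2, 33 replication genes fell and 5 rose, 39 mitosis genes fell and 3 rose, and 14 recombination genes fell and 1 rose. Of 36 histone genes, 30 rose and 6 did not pass, with 31 rising adjusted over the list alone (median log2 fold change 2.60, adjusted p = 3.50e-26; adjusted p = 0.0389 with an estimated correlation, the single list of this comparison to pass in that form). HIST1H2BF rose from 2.56 ± 0.591 to 62.5 ± 1.01 FPKM and HIST1H4D from 0.505 to 8.55 FPKM, and fragments of these near-identical genes may be shared between copies. Of 24 genes of the RB family, cyclins, CDKs and their inhibitors, 5 rose and 2 fell both over all genes and adjusted over the list alone, or 10 and 7 without shControl 2, and the list did not pass (adjusted p = 0.375).

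Inflammatory genes moved in both directions under palbociclib, with more falling. Of 49 NF-kappaB targets 13 fell, 8 rose and 28 did not pass, and adjusted over the list alone 16 fell and 9 rose (adjusted p = 0.0462; adjusted p = 0.103 with an estimated correlation). Members that fell had log2 fold changes of -4.54 (IL1B), -3.14 (IL1A) and -2.76 (CSF2), while the chemokine gene CCL5 rose from 0.0566 to 0.556 FPKM. This list did not pass without DMSO 3 (adjusted p = 0.0565), with the replicate number as a block (0.0511, or 0.0574 with GC and length correction), with limma and a pseudocount of 0.1 (0.0548), with array weights (0.132) or with median-of-ratios factors (0.0521), and without shControl 2 the counts were 25 and 17. Of 43 interferon-stimulated genes 17 fell and 2 rose, or 17 and 3 adjusted over the list alone (adjusted p = 0.0113; adjusted p = 0.124 with an estimated correlation, 0.0662 at 5 FPKM and 0.0529 with array weights). IFIT1, an antiviral gene, fell by 1.72, and RSAD2, which encodes viperin, rose from 0.398 to 2.06 FPKM. Of 29 senescence-associated proteases and growth factors 10 fell and 2 rose, or 11 and 2 adjusted over the list alone (adjusted p = 0.0189; adjusted p = 0.0761 with an estimated correlation). AREG, an EGF receptor ligand gene, fell by 3.03, INHBA by 2.97 and PLAT, the tissue plasminogen activator gene, by 2.83, while the matricellular gene CTGF rose from 4.79 ± 0.556 to 222 ± 6.86 FPKM. Immune checkpoint ligands as a list did not pass (6 rose and 4 fell of 22, 7 and 4 adjusted over the list alone, 10 and 5 without shControl 2, adjusted p = 0.336), nor did MHC class I antigen presentation (1 rose and 2 fell of 20, the same counts adjusted over the list alone, 3 and 4 without shControl 2, adjusted p = 0.80).

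Among lists of metabolism and stress, cholesterol synthesis and hypoxia response passed as lower and the stress response as higher. Of 26 cholesterol genes 9 fell and 2 rose, or 11 and 2 adjusted over the list alone (adjusted p = 0.0189; adjusted p = 0.0761 with an estimated correlation). This call was lost at 5 FPKM (adjusted p = 0.0676), with limma and a pseudocount of 0.1 (0.0589) and with array weights (0.202), and without shControl 2, 14 fell and 7 rose. Of 28 genes of the unfolded protein and integrated stress response 12 rose and 2 fell, or 12 and 3 adjusted over the list alone and 15 and 8 without shControl 2 (adjusted p = 0.0118; adjusted p = 0.0761 with an estimated correlation). The stress factor gene ATF3 rose from 25.5 ± 0.310 to 434 ± 5.71 FPKM, SESN2 by a log2 fold change of 2.02, CHAC1 by 1.93 and HERPUD1 by 1.88. Of 26 hypoxia response genes 9 fell and 3 rose, or 10 and 3 adjusted over the list alone (adjusted p = 0.0450; adjusted p = 0.103 with an estimated correlation), with NDRG1 falling by 2.63, HK2, a hexokinase gene, by 1.31, and the peptide hormone gene ADM rising by 1.85. The hypoxia call was lost with quantile normalization (adjusted p = 0.104) and at 5 FPKM (0.0662), and without shControl 2, 15 fell and 5 rose. MYC and ribosome biogenesis (7 rose and 2 fell of 32, adjusted p = 0.0876), p53 targets (4 rose and 7 fell of 24, adjusted p = 0.467) and lysosome genes (7 rose and 1 fell of 39, adjusted p = 0.0990) did not pass. Adjusted over the list alone these counts were 7 and 2, 5 and 7, and 5 and 1, and without shControl 2, 19 MYC genes rose and 6 fell, and 9 p53 targets rose and 11 fell. The lysosome list passed without shControl 2 (17 rose and 4 fell, adjusted p = 0.0479). Both the lysosome and the MYC list passed with limma on FPKM (adjusted p = 0.0113 and 0.0206) and with GC and length correction (each 0.0107).

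Of the lists of cell identity under palbociclib, 2 passed. Of 25 epithelial genes 4 fell and none rose, the same adjusted over the list alone (adjusted p = 0.0464; adjusted p = 0.103 with an estimated correlation), including the tight junction gene TJP3 (-1.79) and the splicing regulator gene ESRP2 (-1.15), both of which overlap another gene. That list did not pass without DMSO 3 (adjusted p = 0.0565) or palbociclib 1 (0.0538), at 5 FPKM (0.0592) or with median-of-ratios factors (0.0572), and without shControl 2, 13 fell and 3 rose (adjusted p = 0.0118). Of 11 tested neuroendocrine and neural genes 5 rose and 1 fell, the same adjusted over the list alone (median log2 fold change 0.77, adjusted p = 0.0462; adjusted p = 0.103 with an estimated correlation). The granule protein genes CHGA and SCG2 rose, to 0.172 and 0.584 FPKM, which are low levels. SCG3, with no fragment in DMSO and 7 in palbociclib, was at least 3.04-fold higher, and its call was lost with the replicate block. The median of the list is the same with SCG3 at that bound. This list did not pass without shControl 2 (median 0.88, adjusted p = 0.263) or without DMSO 2 (adjusted p = 0.0548), and its median was 1.45 without DMSO 3. The call was also lost with limma on FPKM (median 0.31, adjusted p = 0.291), with a pseudocount of 0.1 (0.77, adjusted p = 0.226) or quantile normalization (0.29, adjusted p = 0.479), with array weights (adjusted p = 0.187), with these groups alone (adjusted p = 0.248) and with GC and length correction (adjusted p = 0.0579). Mesenchymal genes (4 rose and 5 fell of 21, adjusted p = 0.80), androgen receptor and luminal genes (1 and 1 of 10, median -0.04 and mean 0.12, adjusted p = 0.80), blood cell markers (2 and 1 of 8, adjusted p = 0.291) and fibroblast and endothelial markers (2 and 3 of 9, adjusted p = 0.446; 0.0467 with limma on FPKM) did not pass, with the same counts adjusted over the list alone. Without shControl 2 the mesenchymal counts were 8 and 6, those of androgen receptor genes 4 and 2, and those of blood markers 3 and 2.

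The second comparison asked what differed between the libraries labelled shRB1 and shControl, in which RB1 itself was not lower. CD274 rose from 2.97 ± 1.25 FPKM in shControl to 16.0 ± 1.06 FPKM (n = 3 each), a log2 fold change of 2.24 (SE 0.19, edgeR quasi-likelihood adjusted p = 1.08e-05), and PDCD1LG2 rose from 1.10 ± 0.439 to 2.28 ± 0.174 FPKM (log2 fold change 0.84, adjusted p = 5.15e-03). CDKN1A rose from 20.6 ± 1.18 to 96.6 ± 4.54 FPKM (log2 fold change 1.95, adjusted p = 8.02e-06). CDK6 rose from 2.86 ± 1.93 to 12.3 ± 1.55 FPKM (log2 fold change 1.97, adjusted p = 3.66e-03) and CCNE1 fell from 10.2 ± 0.356 to 7.02 ± 0.121 FPKM (log2 fold change -0.82, adjusted p = 2.63e-03). The 3 libraries labelled shRB1 lay on one side of the 3 shControl libraries for all 5 of these genes. CDK4 (-0.42, adjusted p = 0.0911), CCND1 (-0.19, adjusted p = 0.379) and RELA (0.22, adjusted p = 0.140) did not pass. CDK4 passed without shControl 1 (-0.58, adjusted p = 0.0194) and RELA without shControl 2 (0.32, adjusted p = 0.00317).

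In this comparison 9044 genes passed, 4363 higher and 4681 lower in the libraries labelled shRB1. Of these, 8719 also passed without shControl 2, where the count was 11975. The 4 groups share 1 estimate of spread, but shControl 1 to 3 deviated more from their mates (SD 0.897, 1.48 and 0.602). In the other libraries that SD was at most 0.413. With shRB1 and shControl alone in the fit, 4681 genes passed. Such a fit leaves fewer libraries to estimate the spread, but palbociclib and DMSO alone gave more genes, 9322 against 5245. Fewer libraries alone therefore do not account for the lower count, and part of the 9044 calls depends on the spread shared with the other groups. The highest rises began from almost no fragments. ZNF80, a zinc finger gene, had no fragment in shControl and 722 in the libraries labelled shRB1, at least 187-fold higher, and the growth factor gene FGF20 went from 0 to 177 fragments, at least 45.7-fold higher. MC5R, a melanocortin receptor gene, went from 1 fragment to 647 (ratio 501, 95% counting interval 89.7 to 19836), and NR1H4, the bile acid receptor gene, from 3 to 903 (ratio 233, interval 79.6 to 1133). ENAM, an enamel matrix gene, rose from 0.0116 to 2.71 FPKM. NTSR1, a neurotensin receptor gene, fell from 10.5 ± 4.08 to 0.703 ± 0.0802 FPKM (log2 fold change -4.28, SE 0.40, adjusted p = 2.09e-05), and KIF12, a kinesin gene, from 3.21 to 0.325 FPKM. Other large falls shrank without shControl 2, from -3.89 to -2.47 for the mucin gene MUC5AC, from -3.85 to -1.42 for TMEM160, from -3.84 to -1.38 for BCL7C, from -3.73 to -2.31 for CTXN1 and from -3.70 to -2.08 for HAGHL.

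The lists of replication and mitosis again passed as lower, and histones as higher. Of 54 replication and G1/S genes 26 fell and 5 rose, the same adjusted over the list alone (median -0.46, adjusted p = 0.00362; adjusted p = 0.140 with an estimated correlation). That call was lost with quantile normalization (median -0.18, adjusted p = 0.101) and at 5 FPKM (adjusted p = 0.0515). POLD1, a DNA polymerase subunit gene, fell by 2.08 and LIG1, a DNA ligase gene, by 1.56. TK1 and POLA2 fell by 1.38 and 1.36, and without shControl 2 their log2 fold changes were -0.79 and -0.76. Of 52 mitosis genes 27 fell and none rose, the same adjusted over the list alone (median -0.73, adjusted p = 6.21e-06; adjusted p = 0.261 with an estimated correlation). The median was -0.47 without shControl 1, 48 genes fell without shControl 2, and shControl 2 lay 1.08 below its mates on this list (a deviation of -1.08). CDCA3 fell by 1.96 and the kinase gene AURKB by 1.82, while CDC20 and PTTG1 fell by 1.79 and 1.77, or to log2 fold changes of -1.15 and -0.76 without shControl 2. Of 36 histone genes 29 rose and 7 did not pass, the same adjusted over the list alone (median 1.78, adjusted p = 1.76e-10; adjusted p = 0.172 with an estimated correlation), with HIST1H4H rising from 8.25 ± 3.58 to 206 ± 11.6 FPKM. Homologous recombination genes (1 rose and 9 fell of 25, none and 7 adjusted over the list alone, adjusted p = 0.0864) passed without shControl 2 (17 fell, median -0.41, adjusted p = 0.00927), with GC and length correction (adjusted p = 6.95e-04) and with no filter (adjusted p = 0.0263). The RB family list did not pass (4 rose and 2 fell of 24, the same adjusted over the list alone, 5 and 7 without shControl 2, median -0.04 and mean 0.19, adjusted p = 0.730).

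The NF-kappaB list passed as higher in the libraries labelled shRB1. Of 49 tested, 32 rose, 10 fell and 7 did not pass, and adjusted over the list alone 32 rose and 11 fell (median 1.25, adjusted p = 6.21e-06; adjusted p = 0.0106 with an estimated correlation). IL6, the interleukin-6 gene, rose from 36.6 ± 13.9 to 939 ± 16.5 FPKM (log2 fold change 4.48, SE 0.17, adjusted p = 1.45e-07). The chemokine genes CCL2 and CCL5 rose from 0.0883 to 11.9 FPKM and from 0.190 to 4.85 FPKM, and TRAF1, a signalling adaptor gene, from 0.376 to 9.81 FPKM. shControl 2 deviated from its mates by -0.11 on this list. Interferon-stimulated genes moved both ways (9 rose and 13 fell of 43, the same adjusted over the list alone, adjusted p = 0.742), as did checkpoint ligands (10 rose and 5 fell of 22, the same adjusted over the list alone, adjusted p = 0.228). Senescence-associated factors (9 rose and 16 fell of 29, the same adjusted over the list alone, adjusted p = 0.133) passed without shControl 2 (median -0.59, adjusted p = 0.0379) and with GC and length correction (adjusted p = 0.0278). MHC class I genes (1 rose and 7 fell of 20, the same adjusted over the list alone, adjusted p = 0.0815) passed without shControl 1 (-0.66, adjusted p = 0.0242) or shControl 3 (-0.58, adjusted p = 0.0383) and with no filter (adjusted p = 0.0200). Their median of -0.47 became -0.17 without shControl 2 (4 rose and 8 fell, adjusted p = 0.361), which lay above its mates by 1.02 on this list.

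The hypoxia response and epithelial lists passed as lower in the libraries labelled shRB1. Of 26 hypoxia genes 15 fell and 2 rose, or 16 and 2 adjusted over the list alone (median -0.98, adjusted p = 0.00162; adjusted p = 0.0407 with an estimated correlation). NDRG1 fell from 539 ± 113 to 150 ± 3.12 FPKM, CA9, a carbonic anhydrase gene, fell by 2.41 on the log2 scale, and ADM rose by 1.76. TPI1, a glycolytic enzyme gene, fell by 1.92, and its log2 fold change was -0.82 without shControl 2. Of 25 epithelial genes 13 fell and 1 rose, the same adjusted over the list alone (median -0.89, adjusted p = 0.0159; adjusted p = 0.104 with an estimated correlation), and that call was lost with quantile normalization (median -0.30, adjusted p = 0.132) and at 5 FPKM (adjusted p = 0.0559). TJP3 fell by 2.04 and the claudin gene CLDN1 rose by 2.27. CLDN3, another claudin gene, fell by 2.31, and its log2 fold change was -1.28 without shControl 2. Of 11 neuroendocrine genes 7 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 2.51, adjusted p = 0.0126; adjusted p = 0.197 with an estimated correlation), with SCG2 rising from 0.228 ± 0.114 to 4.26 ± 0.194 FPKM. ELAVL3, a neuronal RNA-binding protein gene, went from 2 fragments to 191 (ratio 74.0, 95% counting interval 20.2 to 616). The neuroendocrine call was lost with limma on FPKM (median 0.66, adjusted p = 0.255), with a pseudocount of 0.1 (0.79, adjusted p = 0.267) or quantile normalization (0.30, adjusted p = 0.449), with array weights (0.40, adjusted p = 0.192), and without shControl 2 with GC and length correction (adjusted p = 0.0641).

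The remaining lists did not pass in the libraries labelled shRB1. The unfolded protein and integrated stress list (11 rose and 4 fell of 28, adjusted p = 0.0864) passed without shControl 2 (16 rose and 7 fell, median 0.41, adjusted p = 2.24e-04), with limma on FPKM (0.70, adjusted p = 0.0205), at 5 FPKM (0.66, adjusted p = 0.00844) and with GC and length correction (adjusted p = 0.00560). Cholesterol synthesis (7 rose and 11 fell of 26, adjusted p = 0.481), lysosome (11 and 15 of 39, adjusted p = 0.755), MYC and ribosome biogenesis (8 and 3 of 32, 12 and 6 without shControl 2, median 0.09 and mean -0.13, adjusted p = 0.842) and p53 targets (7 and 3 of 24, adjusted p = 0.445) moved both ways. Mesenchymal genes (6 and 8 of 21, adjusted p = 0.911) had a median of -0.42 and a mean of 0.30. Within that list SNAI2 and ZEB2, repressors of epithelial genes chosen after their values were seen, rose by 3.64 and 3.35. Androgen receptor and luminal genes (2 and 2 of 10, 3 and 4 without shControl 2, median 0.03 and mean -0.04, adjusted p = 0.905), blood markers (4 and 2 of 8, adjusted p = 0.294) and fibroblast and endothelial markers (2 and 5 of 9, adjusted p = 0.280; 0.0457 with limma and a pseudocount of 0.1) did not pass. Adjusted over the list alone, 12 cholesterol genes and 16 lysosome genes fell, 2 p53 targets fell, 8 mesenchymal genes rose and 9 fell, and the other counts were the same.

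**Figure D3:**
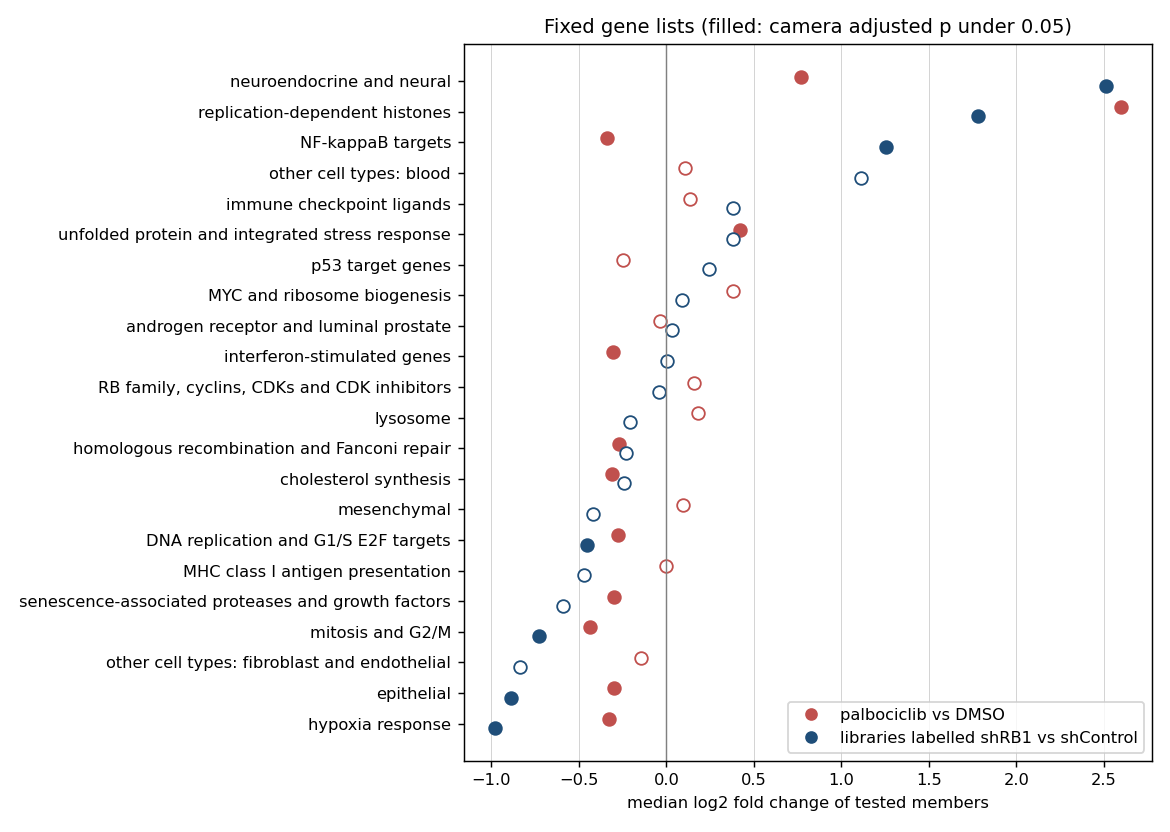
Each row gives a fixed gene list and the median log2 fold change of its tested members, in red for palbociclib against DMSO and in blue for the libraries labelled shRB1 against shControl, filled where the camera adjusted p is under 0.05. Histones lie at 2.60 and 1.78, and the NF-kappaB list lies on opposite sides of 0, at -0.34 and 1.25.

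The third comparison asked which genes moved differently under palbociclib than in the libraries labelled shRB1, by the difference of the 2 effects. CD274 rose in both, and the difference was -0.20 (95% interval -0.71 to 0.32, adjusted p = 0.606). PDCD1LG2 fell under palbociclib and rose in the libraries labelled shRB1 (difference -2.52, SE 0.28, adjusted p = 2.67e-04). The NF-kappaB list moved apart, with 29 of 49 genes lower under palbociclib by this difference, 1 higher and 19 not passing, and 30 and 1 adjusted over the list alone (median difference -1.42, adjusted p = 2.44e-13; adjusted p = 7.47e-04 with an estimated correlation). IL6 differed by -5.22 (SE 0.22, adjusted p = 1.38e-06), IL1A by -5.65 and CSF2 by -3.65. CDKN1A rose more under palbociclib (difference 1.15, adjusted p = 4.10e-03). RB1 (-0.71, adjusted p = 0.614), CDK4 (0.58, adjusted p = 0.138), CDK6 (-1.55, adjusted p = 0.0799), CCND1 (0.08, adjusted p = 0.839), CCNE1 (0.06, adjusted p = 0.866) and RELA (-0.47, adjusted p = 0.0671) did not pass. Without shControl 1, CDK4 (0.74, adjusted p = 0.0394) and CDK6 (-1.98, adjusted p = 0.0235) passed, and without shControl 2, CDK6 (-1.18, adjusted p = 0.0141) and RELA (-0.57, adjusted p = 8.50e-04) passed.

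In the difference of effects 4021 genes passed, 1878 positive and 2143 negative. The count was 8704 without shControl 2, 6228 without shControl 1, 2610 and 2469 without DMSO 1 and 2, 2665 and 2585 without palbociclib 2 and 3, and 2555 and 2539 without shRB1 2 and 3. RASD1, a small GTPase gene, stood at 2.23 FPKM in DMSO, 247 in palbociclib, 3.04 in shControl and 11.9 in the libraries labelled shRB1 (difference 5.12, SE 0.36, adjusted p = 2.25e-05). FAM229A stood at 0.826, 9.34, 2.21 and 0.651 FPKM in the same order (difference 5.61, SE 1.02, adjusted p = 3.73e-03). The antimicrobial gene RNASE7 and the ubiquitin-like modifier gene UBD had no fragment in palbociclib and 308 and 301 in the libraries labelled shRB1, so their fitted differences of -9.38 and -8.89 depend on the prior count. Of the other lists, interferon-stimulated genes had 16 negative and 4 positive differences of 43, 16 and 5 adjusted over the list alone (median -0.68, adjusted p = 0.00390; adjusted p = 0.335 with an estimated correlation), with a median of -0.42 without shControl 2. With limma on FPKM that call was lost (adjusted p = 0.0528, or 0.0560 with a pseudocount of 0.1, 0.0507 with quantile normalization and 0.0773 with array weights). Mitosis genes had 9 positive and no negative differences of 52, the same adjusted over the list alone (median 0.37, adjusted p = 0.0276; adjusted p = 0.685 with an estimated correlation). This call was lost without shControl 1 (0.16, adjusted p = 0.195) or shControl 3 (0.25, adjusted p = 0.123), and without shControl 2 the median was 0.57, with 34 positive and no negative differences. It was also lost with limma on FPKM (0.02, adjusted p = 0.0820), with a pseudocount of 0.1 (-0.00, adjusted p = 0.0942) or quantile normalization (0.11, adjusted p = 0.234), and at 5 FPKM (0.24, adjusted p = 0.108). Histones had 11 positive and 2 negative differences of 36, 15 and 2 adjusted over the list alone (median 0.84, adjusted p = 0.00111; adjusted p = 0.371 with an estimated correlation). That call was lost without shControl 2 (0.38, adjusted p = 0.0940), and after the GC and length correction the median was -0.25 (adjusted p = 0.947). The other 18 lists did not pass, with adjusted p from 0.180 to 0.959. Median and mean differed in sign for homologous recombination (0.03 and -0.10), senescence-associated factors (0.19 and -0.02), stress response (-0.10 and 0.05) and mesenchymal genes (-0.10 and 0.03). The lists of p53 targets, cholesterol synthesis and hypoxia response passed without shControl 2 (medians -0.21, -0.31 and 0.53), each at adjusted p = 0.0492.

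Across genes, the log2 fold changes of the 2 comparisons, which share no library, had a Pearson r of 0.53 and a Spearman rho of 0.43. Genes are not independent replicates, so no p is given. Of the genes that passed in both, 1708 rose in both, against 670 for independent lists, and 1255 fell in both, against 679. Opposite calls numbered 152 (palbociclib up, labelled shRB1 down) and 344 (palbociclib down, labelled shRB1 up), against 719 and 633. Without shControl 2, 3109 rose in both (against 1762) and 3014 fell in both (against 1776), and opposite calls numbered 669 and 846 (against 1733 and 1805). CDKN1A and CD274 were among the genes that rose in both, NDRG1 and CCNE1 among those that fell in both.

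**Figure D4:**
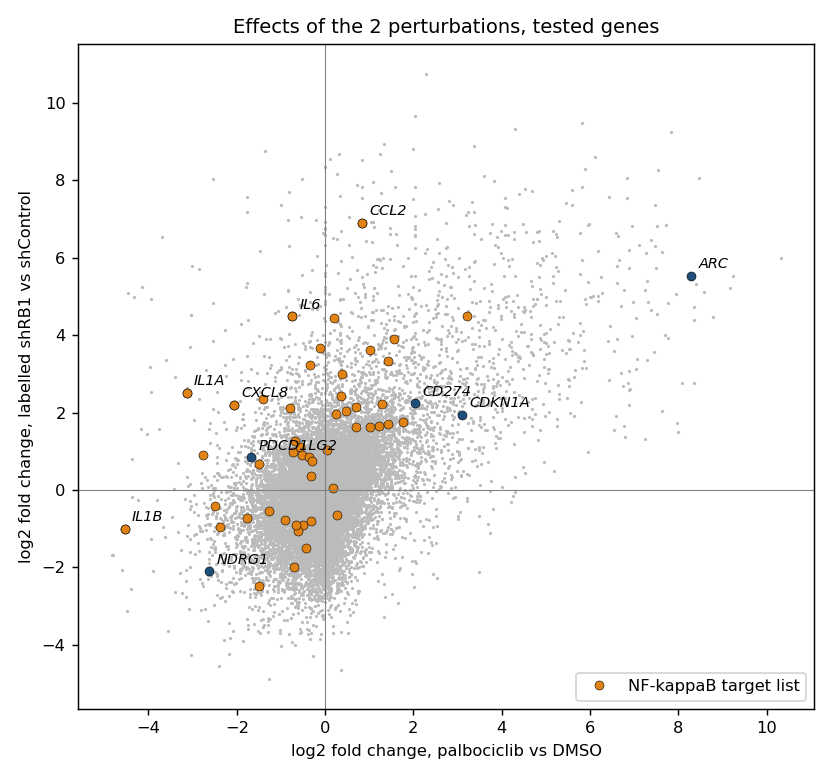
Each point is 1 of 17561 tested genes, with its log2 fold change for palbociclib against DMSO on the x axis and for the libraries labelled shRB1 against shControl on the y axis. Orange points are the 49 tested NF-kappaB targets and blue points are further genes named in the text. IL6 lies at -0.74 and 4.48, and CD274 at 2.04 and 2.24.

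The control groups were compared to scale differences between sets of libraries that are not the perturbations of interest. Between shControl and DMSO 1643 genes passed, 1043 higher and 600 lower in shControl, or 102 with these 2 groups alone in the fit. Among the fixed genes CDKN1A was higher (0.77, adjusted p = 0.0121). That call was lost without DMSO 1 (0.78, adjusted p = 0.0542) or DMSO 2 (0.73, adjusted p = 0.0683). CD274 (0.18, adjusted p = 0.536) and RB1 (-0.50, adjusted p = 0.643) did not pass, though CD274 did without shControl 2 (0.35, adjusted p = 0.0369). MYC and ribosome biogenesis genes were higher as a list (11 rose and none fell of 32, 17 and none adjusted over the list alone, adjusted p = 2.22e-05; adjusted p = 0.0115 with an estimated correlation). The stress response list was lower (8 fell of 28, 10 adjusted over the list alone, adjusted p = 6.61e-05; adjusted p = 0.0115 with an estimated correlation), as was cholesterol synthesis (6 fell and 1 rose of 26, 10 and 2 adjusted over the list alone, adjusted p = 6.91e-04; adjusted p = 0.0208 with an estimated correlation). Mitosis genes (4 fell of 52, 2 adjusted over the list alone, adjusted p = 2.86e-06) and blood markers (3 fell of 8, 4 adjusted over the list alone, adjusted p = 6.91e-04) were also lower, both at adjusted p = 0.282 with an estimated correlation. Without shControl 2 the mitosis median went from -0.50 to -0.28, with 25 genes falling, and 21 MYC genes rose, 17 stress and 19 cholesterol genes fell and 5 blood markers fell. Without that library, MHC class I genes (adjusted p = 1.03e-06), histones (3.36e-04) and epithelial genes (0.00550) also passed as lower, and interferon-stimulated genes (0.00697) and fibroblast and endothelial markers (0.00206) as higher. Leaving out 1 library other than shControl 3 moved the count of genes by over 1.5 times, to 628, 599 and 880 without DMSO 1 to 3, 1092, 1057 and 1062 without palbociclib 1 to 3, 3396 and 5239 without shControl 1 and 2, and 1022, 983 and 1037 without shRB1 1 to 3.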

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

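The tests chosen only after the result was seen were, for RB1, the interval without shControl 2, the correlation of the libraries labelled shRB1 and the RB1 value without shControl 2, for the NF-kappaB list the value without shControl 2, and the splits for the lists of shControl against DMSO. The GC and length correction was added after the data were seen. The number of random splits of the 12 libraries was raised to 100 after the values of fewer splits had been seen. The rule by which the split count of genes in the difference of effects does not decide was also added after its values were seen.

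The NF-kappaB list passed in opposite directions under palbociclib and in the libraries labelled shRB1, and the difference itself passed (median difference -1.42, adjusted p = 2.44e-13, with adjusted p from 5.6e-40 to 7.5e-04 over its alternatives). RB1 was not lower in the libraries labelled shRB1, so the contrast is between the drug and a label. GC and length bias as the whole cause is argued against by the adjusted p of 4.96e-16 after the correction, and shControl 2 as the whole cause by 2.33e-33 without it. The fall under palbociclib alone is weaker, with adjusted p = 0.0462, and the call is lost with an estimated correlation (0.103), without DMSO 3 (0.0565), with the replicate block (0.0511) and, at its weakest, with array weights (0.132). No biological explanation was tested.

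Other results with opposite calls and a difference past the threshold are single genes, searched for only among those that the naming rule covers. Genes outside that rule, such as MYC, can meet the same condition. PDCD1LG2 differed by -2.52, with -1.68 under palbociclib and 0.84 in the libraries labelled shRB1. The cytokine genes differed by -5.65 (IL1A), -5.22 (IL6), -3.65 (CSF2) and -6.75 (CXCL10, from 25 to 2 fragments under palbociclib). HAS2 differed by -5.49, INSIG1, a brake on cholesterol synthesis, by -3.15, and CCNE2, the cyclin E2 gene, by -2.28, with a rise of 0.78 in the libraries labelled shRB1 that was 0.47 without shControl 2. RNASE7 differed by -9.38, a fitted value that depends on the prior count because palbociclib held no fragment. FAM229A differed by 5.61, or 4.07 without shControl 2, where its value in the libraries labelled shRB1 was -0.58 (adjusted p = 0.0865) in place of -2.12.

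The RB1 transcript was not lower in the libraries labelled shRB1. Without shControl 2, the lower end of the 95% interval, -0.38, argues against the spread of shControl hiding a fall of 2-fold or more. After the correction the lower end, -0.62, argues against GC and length bias hiding such a fall. Both ends lie above -1, but smaller falls, to 0.77-fold and 0.65-fold, stay within the intervals. A swap of shControl 2 with a library labelled shRB1 is argued against because the lowest mean correlation of those libraries with their mates was 0.9955. In shControl 2, RB1 lay at percentile 1 of 200 genes of like GC content and size (deviation -3.71, median of these genes -1.61), which is consistent with RB1 being lower there beyond that bias, and in DMSO 3 it lay at percentile 5.5. No knockdown and a knockdown that total fragments do not show, such as one acting on protein, cannot be told apart by the RB1 value of 0.18 without shControl 2, because no exon or protein level was analysed here.

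In the libraries labelled shRB1, 71 of 8174 genes that were under 0.1 FPKM in every shControl library reached at least 1 FPKM in all 3 libraries, against 32 of 8524 under palbociclib, and none was lost in that sense in either. With shControl 2 left out of the condition the count was 85. All libraries were thinned to the same number of fragments. The lowest library labelled shRB1 then still had 972 more genes with at least 10 fragments than the highest shControl library. This argues against depth as the cause of the higher count of detected genes. The 71 genes themselves were not examined after thinning. These genes overlapped another gene in 25.4% of cases against 30.9% of those that stayed silent (odds ratio 0.759, 95% interval 0.418 to 1.32, Fisher's exact test two-sided p = 0.367). Fragments of overlapping genes are argued against as the cause for the set as a whole, since most of its genes overlapped no other. For the genes that do overlap this cause stays open, because whether the overlapped genes were expressed or rose was not examined. No biological explanation was tested, nor was a difference between clones or vectors.

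Other splits of the same libraries were also fitted. For palbociclib against DMSO the real split gave 5245 genes and the highest of the others 0 (1 of 10 splits as large), and 12 lists against 8 (1 of 10). For shRB1 against shControl it gave 9044 genes against 0 (1 of 10) and 7 lists against 7 (2 of 10), the other split being shControl 1, shControl 3 and shRB1 1 against the rest. For shControl against DMSO it gave 1643 genes against 0 (1 of 10) and 5 lists against 5 (2 of 10), the other split being DMSO 1, DMSO 3 and shControl 2 against the rest. In each, 10 splits are too few for a share under 0.05, and the other splits mix groups that differ, which fixes their 0 genes, so they are no reference without effect. For the difference of effects, of 100 splits of the 12 libraries drawn at random, the real one included, 2 gave as many genes (4021 in the real one, 4494 in a split that kept the 3 libraries labelled shRB1 together), but this test does not decide whether chance is excluded for the count of genes. All 93 splits that kept no group whole gave 0 genes, since mixing groups that differ raises the spread, so their outcome was fixed. Chance is not excluded for the count of lists, where 59 of 100 splits gave at least the real 4 and the highest of the others 10, nor for the correlation across genes, where 26 of 100 splits, counting either sign, reached the size of 0.53 and the highest of the others was 0.82 in size (r = -0.82). These splits also put differences between the groups into both effects, so for lists and correlation they are no reference without effect and leave chance open.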

How the results depend on the processing

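The GC and length correction, that correction with the replicate block, palbociclib and DMSO alone with the block, and the settings without DMSO 3 and shControl 2 and without shControl 2 with the correction were chosen after the data were seen. Over 161 results of named genes and 66 of lists, 5992 single settings gave the same call in 5645 (129 of them uncalled values that changed sign), lost it in 179, gained it in 163, and in 5 changed sign with a call in only one of the 2 fits, and the cause was not tested unless stated. Those 5 were newly called values of the other sign for CCND1 with array weights in the libraries labelled shRB1 (0.15) and in the difference (-0.31, and -0.24 without DMSO 3 and shControl 2), and CCNE1 with array weights in the difference (-0.12), and a lost call of the histone list in the difference after GC and length correction (-0.25, adjusted p = 0.947). Array weights ran from 0.00316 (shControl 2) to 90.1 (shControl 3), and their estimation stopped before it converged, so values with them rest on few libraries.

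For palbociclib against DMSO, 5245 genes became 3403 with a pseudocount of 0.1, 2789 at 5 FPKM (fewer genes tested), 3136 at a log2 fold change of at least 1, 9322 with these groups alone, 10119 with them alone and blocked, 12378 with array weights, 11697 without DMSO 3 and shControl 2, 12191 without shControl 2 with GC and length correction, and 3915 to 10584 leaving out 1 library. Its 12 lists became 1 with an estimated correlation and 20 with fry (10 to 12 leaving out 1 library). For shRB1 against shControl, 9044 genes became 5257 at 5 FPKM, 4681 with these groups alone and 6895 to 11975 leaving out 1 library, and 7 lists became 2 with an estimated correlation, 16 with fry and 11 without DMSO 3 and shControl 2 (7 to 10 leaving out 1 library). For the difference, 4021 genes became 12392 with array weights, 2423 at 5 FPKM, 6385 with GC and length correction, 10551 without DMSO 3 and shControl 2, 10487 without shControl 2 with that correction and 2469 to 8704 leaving out 1 library. Its 4 lists became 2 with each limma setting on FPKM (pseudocount 1 or 0.1, quantile normalization, no trend), 1 with an estimated correlation and 9 with fry (3 to 6 leaving out 1 library). For shControl against DMSO, 1643 genes became 888, 840 and 934 with limma (pseudocount 1, 0.1, no trend), 12622 with array weights, 938 at 5 FPKM, 814 with the replicate block, 102 with these groups alone, 810 at a log2 fold change of at least 1, 3409 with DESeq2, 3694 with GC and length correction, 6738 without DMSO 3 and shControl 2, 7676 without shControl 2 with the correction and 599 to 5239 leaving out 1 library. Quantile normalization moved its split from 1043 higher and 600 lower to 841 and 797.

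The r of 0.53 across genes became 0.41 with limma (0.44 with a pseudocount of 0.1, 0.42 with quantile normalization, 0.41 with no trend, 0.43 with array weights), 0.42 with no filter, 0.44 at 5 FPKM, 0.56 with GC and length correction, 0.56 without DMSO 3 and shControl 2, 0.58 without shControl 2 with the correction and 0.49 to 0.58 leaving out 1 library. The values with the correction (0.564) and without shControl 2 (0.576) were also run as tests of bias and of shControl 2 as causes of this r and argued against both, and they are not weighed further. Limma on FPKM shifted the median of all genes to 0.20 for shRB1 against shControl and to -0.19 for the difference, from 0.01 and 0.02. The replicate block ended the calls of the NF-kappaB list (adjusted p = 0.0511), FANCD2 (0.0555) and SCG3 (0.0546) for palbociclib. For the difference it ended those of NPPB (0.114) and GALR3 (0.0565). It changed no other call of a named gene or list that palbociclib against DMSO enters. With the block, GC and length correction gave 7289 genes and 13 lists for palbociclib against DMSO. Most 2-fold changes were missed in the simulation. It changed far fewer genes than passed here, so its recovery need not hold for these libraries. Of the 5245 genes that passed for palbociclib, 1756 rose and 1380 fell by at least 2-fold, so smaller changes passed too.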

Other observations

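The following regulators lie outside the fixed rule and were chosen after their values were seen. MYC, a growth regulator, fell from 98.9 ± 3.28 to 16.4 ± 0.262 FPKM under palbociclib (log2 fold change -2.61, adjusted p = 2.59e-05) and rose from 102 ± 51.3 to 266 ± 10.2 FPKM in the libraries labelled shRB1 (1.23, adjusted p = 1.59e-03), a difference of -3.83 (adjusted p = 6.44e-05). PLK2, a p53 target that encodes a kinase, fell by 2.97 and rose by 1.80, and the CDK inhibitor gene CDKN1C rose by 1.57 and fell by 1.42 (log2 fold change -0.55 without shControl 2). CDKN2B, another CDK inhibitor gene, rose in both, by 0.79 under palbociclib and by 2.25 in the libraries labelled shRB1. SQSTM1, an autophagy receptor gene, rose from 169 ± 8.34 to 1085 ± 55.0 FPKM in the libraries labelled shRB1, in which RB1 was not lower. Of the left-out libraries, only shControl 2 was run for these genes, and each of these calls passed without it.

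More genes were detected in the libraries labelled shRB1. Thinned to the same number of fragments, the libraries had on average 14901 ± 21.2 genes with at least 10 fragments in DMSO, 15331 ± 11.5 in palbociclib, 14903 ± 357 in shControl and 16098 ± 12 in the libraries labelled shRB1 (SD, n = 3 each). shControl 2 had 14490, and shControl 1 and 3 had 15104 and 15114. Of 7887 genes silent in both control groups 19 appeared under palbociclib and 61 in the libraries labelled shRB1, and 7 appeared in both, against 0.147 for independent sets: LINC01467, OTOP2, KIAA1683, FCGR1A, CCR4, C6orf222 and BAAT. The value of 0.147 takes all 7887 genes as equally able to appear, which was not tested, so no conclusion is drawn from the excess. FCGR1A overlaps HIST2H2BF, so the origin of its fragments is uncertain. Among the genes that appeared in the libraries labelled shRB1 were the interferon gene IFNL1 and the albumin gene ALB. Among those that appeared under palbociclib were the lymphocyte receptor gene BTLA and the transcription factor gene POU4F3.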
